A study of Mus musculus with 6 samples.

How the data were processed

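Liver RNA of 6 mice aged 5 weeks was profiled on one-colour (Cy3) Agilent mouse arrays, 1 array per sample, with 3 control and 3 sMaf CKO samples on a mixed strain background. Per the labels' protocols, total RNA was extracted from liver tissue, purified on columns, and 500 ng of it was amplified and labelled. Samples were grouped by the genotype in the labels, and replicate numbers come from the sample titles.

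Per the file headers, spot intensities were extracted by the authors with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09. The deposited processed intensity of a spot is background-subtracted and spatially detrended within its array, with no step between arrays recorded in the headers. The headers name mouse build mm9 for the array design, while the gene table used for names is on GRCm38.p6, so no coordinates are given. The deposited value table of the series holds log2 values, and how the authors made it is not given in the sources used here. Set against the scanner files, its columns equal log2 of the processed intensity minus the array's 75th percentile, centred for each probe on the median of the 6 arrays (r = 1 on each array over 22635 probes, with 99% of differences within 0.00223). Its direction, scale and centring are therefore settled, and its column medians are 0.05, -0.02, 0.08, -0.10, -0.11 and 0.09 in the order control 1, 2, 3 and sMaf CKO 1, 2, 3.

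The main values were log2 processed intensities, averaged over the spots of each probe, minus each array's 75th percentile of these averages over non-control probes. Control spots and spots with an outlier flag were left out, spots of one probe were averaged, and probes well above background on at least 3 of the 6 arrays were kept (27859 of 41174). No kept probe was saturated, and 47 tested probes had a value left out as an outlier on at least 1 array. The files carry no gene names, so each probe was named through its transcript accession in the gene table. This matched 26690 probes to 1 symbol each (18217 symbols) and left 14484 unmatched, which were tested under their accession. For a gene with several kept probes the one with the highest mean over all 6 arrays was used. Of the 18 changed genes with several kept probes, 0 had probes of opposite sign. In all, 21059 genes and transcripts were tested, 14213 of them with a symbol.

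Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype alone in the model), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A gene not well above background on any array of a group has only a bound there. Its fold is given as at least the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Gene lists with at least 3 tested members were compared with all other genes by camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Of 704 genes in the lists, 652 were tested. As alternatives, camera was run with a correlation estimated for each list (from -0.156 to 0.854, median 0.287) and fry was run on each list. A list score of an array is the mean difference of its members from their control means.

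The text names every small Maf gene and partner, and the 12 largest fitted rises and 12 largest fitted falls among changed genes with a symbol whose arrays do not overlap. Predicted genes named only by an accession, clone or locus number were counted but passed over in these rankings. For each list it names up to 4 changed members or else the 2 with the smallest p. Like the lists, the naming rule, the tests and most alternatives were fixed beforehand. These alternatives were normexp background correction (offset 50), quantile normalization, median scaling, the authors' value table, other filters on dim probes, the mean of a gene's probes, a replicate block, a slide block, array weights, eBayes with trend and robust settings, each array left out in turn, an adjusted p under 0.01 and a minimum log2 fold change of 1. Scaling on bright E1A spike-in probes and fits within each slide were chosen after seeing the data. The files hold no mean spot signal, so normexp used the median spot and local background signals in its place. Spike-in scaling raises the fold change of every gene by about 0.32 on the log2 scale, so list medians between -0.32 and 0 turn positive under it without a change relative to other genes.

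The gene and list tests were run on simulated data with the variances of these arrays (21012 genes). Of genes changed by 1, 2 and 4 on the log2 scale, 4.48%, 86.6% and 98.5% were called, with 9 false calls among unchanged genes and 0 in the wrong direction. A list of 34 genes shifted by -0.5 was called and no other list was. Over 20 simulated sets with no change, the highest count was 0 genes and 1 list. Genes were drawn independently of each other, whereas the estimated correlation within the real lists had a median of 0.287. The simulated list counts therefore do not show how often lists are called falsely on these arrays. In these simulations, changes near 1 on the log2 scale were seldom called with 3 arrays per group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.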

Results

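RNA levels were measured in livers of mice at 5 weeks of age on 6 one-colour Agilent arrays, 3 from mice with a liver-specific knockout of small Maf genes (sMaf CKO) and 3 from control wild-type mice. The small Maf proteins MafF, MafG and MafK are bZIP transcription factors that lack a transactivation domain and bind DNA as partners of the CNC and Bach factors, among them NRF1 and NRF2. The comparison asks which liver transcripts differ in level between sMaf CKO and control liver. The submitters describe the RNA samples of a genotype as independent of each other. The labels state neither which of the small Maf genes were deleted nor the sex of the mice. Over non-control spots, the 75th percentile of the processed signal was 604.9, 638.2 and 499.5 on control arrays 1, 2 and 3, and 1013, 708.3 and 507.9 on sMaf CKO arrays 1, 2 and 3. Between 58.0% and 73.6% of probes were well above background on an array. Across probes, arrays of the same genotype correlated at r = 0.970 to 0.984 and arrays of different genotypes at r = 0.953 to 0.980. The first principal component held 44.0% of the variance and parted the genotypes, with scores of -61.19 to -16.99 for control arrays and 18.58 to 73.47 for sMaf CKO arrays. The arrays lay on 2 slides, with replicates 1 and 2 of both genotypes on slide 1 and replicate 3 of both on slide 2. A value within slide 2 therefore compares 1 array with 1. The slide 2 arrays had the lowest shares of probes well above background, 58.04% for control and 58.65% for sMaf CKO.

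The signal of Mafg was far lower in sMaf CKO liver, whereas those of Maff and Mafk were not detectably different. Relative to the 75th percentile of the array, the log2 level of Mafg was 1.995 ± 0.20 (SD, n = 3) in control and -2.70 ± 1.82 (SD, n = 3) in sMaf CKO liver, a difference of -4.69 (SE 0.79) or 25.9-fold. The 3 sMaf CKO arrays kept 3.20%, 1.22% and 14.8% of the control mean, the last of these being replicate 3. In limma's test over all genes this difference just missed the threshold (adjusted p = 0.0533). It passed with slide as a block (adjusted p = 0.0207) and without sMaf CKO replicate 3 (difference -5.66, adjusted p = 0.00484), and it was -5.55 within slide 1 and -2.99 within slide 2. Maff differed by 0.15 (SE 0.51, adjusted p = 0.911; 0.22 within slide 1 and 0.01 within slide 2). Mafk differed by 0.21 (SE 0.29, adjusted p = 0.759; 0.45 within slide 1 and -0.29 within slide 2). The sign of the Maff difference turned without control replicate 2 (-0.37) or sMaf CKO replicate 3 (-0.11), and that of Mafk without control replicate 2 (-0.07). Each gene was read by 1 probe, and whether these probes lie inside the deleted part of a gene is not known, so the levels of Maff and Mafk do not check the labels. As a list, the 3 genes had a median of 0.15 but a mean of -1.45 and did not pass (camera adjusted p = 0.471).

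**Figure D1:**
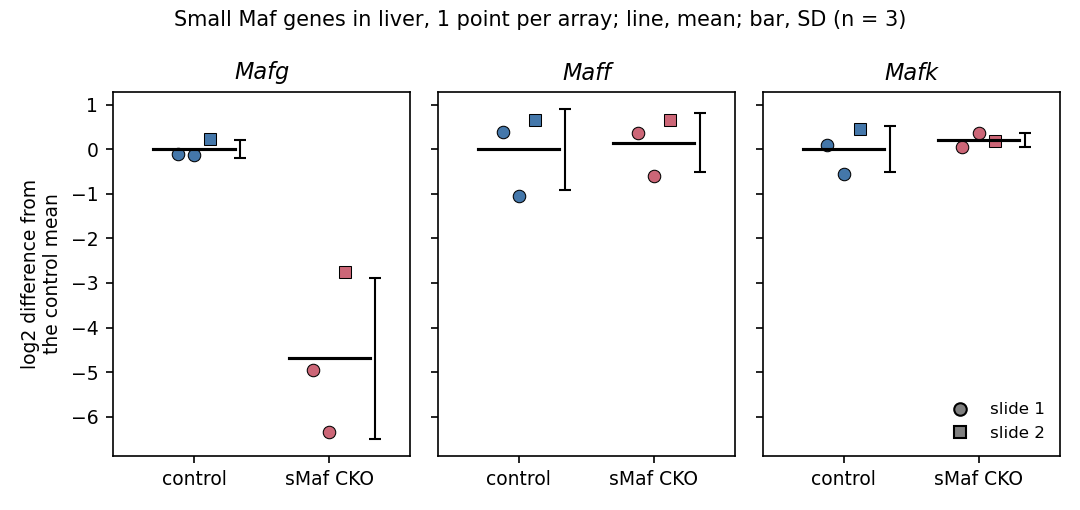
Log2 signal of Mafg, Maff and Mafk on each array as the difference from the control mean (y axis), for 3 control and 3 sMaf CKO arrays, with the shape of a point giving the slide, the line the mean and the bar the SD. Mafg kept 3.20%, 1.22% and 14.8% of the control mean on the 3 sMaf CKO arrays, while the groups overlapped for Maff and Mafk.

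Among 21059 genes and unmatched transcripts tested with limma, 114 changed at a Benjamini-Hochberg adjusted p under 0.05, of which 81 rose and 33 fell in sMaf CKO liver. Among genes with a symbol, 65 rose and 21 fell. Of the changed genes named here, Slpi and S100g had the largest rises among those well above background on every array. The largest falls among them were in Serpina4-ps1, Ces1f and Cyp7b1. Gpnmb, a glycoprotein of phagocytes and other cells, was not well above background on any control array and rose at least 22.2-fold (adjusted p = 0.0117). Myo5c, an unconventional myosin of epithelial cells, was likewise dim in controls and rose at least 18.2-fold (adjusted p = 0.0131). Slpi, a secreted inhibitor of leukocyte proteases, rose 35.2-fold (log2 fold change 5.14, SE 0.61, adjusted p = 0.0290). S100g, a small calcium-binding protein, rose 25.3-fold (adjusted p = 0.0105), and Trem2, a receptor of macrophages measured on 2 of 3 control arrays, rose 18.1-fold (adjusted p = 0.0105; log2 fold change 4.18, against 2.86 by its other probe). Elf3, an ETS factor of epithelia measured on 2 of 3 control arrays, rose 22.0-fold, or 13.2-fold with the dim array raised to the lowest signal above background, and Gsta2, a glutathione S-transferase, 21.7-fold. Psrc1 and Cdkn1a, which encodes the cell cycle inhibitor p21, rose 15.4-fold and 15.3-fold, with log2 fold changes between 2.89 and 3.94 over the 3 probes of Psrc1. The other members of the 12 largest fitted rises were Cyp2c55 (14.9-fold), the stress-induced gene Nupr1 (13.5-fold) and Spink1, a trypsin inhibitor (11.7-fold).

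Of the genes that fell, the transcribed pseudogene Serpina4-ps1 fell by 4.96 on the log2 scale (SE 0.77, adjusted p = 0.0485, with -5.51 by its other probe), Ces1f, a carboxylesterase, by 3.97 (SE 0.49, adjusted p = 0.0357) and Cyp7b1, an oxysterol hydroxylase of bile acid synthesis, by 3.75 (SE 0.32, adjusted p = 0.0117). The serine protease Htra4 was 8.11-fold lower, Cyp2c54 6.15-fold and the serpin Serpina3j 5.27-fold. Fitm1, a gene linked to lipid droplet formation and well above background on 2 of 3 sMaf CKO arrays, was 5.08-fold lower, or 4.93-fold with the dim array raised likewise. Pir, which encodes the iron-binding protein pirin, fell 4.30-fold, Tafa2 4.28-fold and Akr1d1, a steroid reductase of bile acid synthesis, 3.83-fold. Ces1g fell 3.70-fold and Stard4, a cholesterol transfer protein, 3.70-fold. The Ces1, Cyp2c, Gsta and Serpina genes have close paralogs, and the probe sequences were not used here to test whether a probe also reads them. Every one of the 114 genes changed by at least 1.26 on the log2 scale, and in all 114 the arrays of the genotypes did not overlap; over all genes tested 22.9% did not overlap, against 10% by chance.

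The number of genes called varied with the model and the arrays used. With slide as a block, which leaves the fold changes of this balanced layout as they are, 340 genes changed (209 rose, 131 fell), all 114 among them. Of the 12 largest fitted rises, the 8 well above background on every array lay between 3.65 and 4.80 within slide 1 and between 2.72 and 5.80 within slide 2. The 11 such falls lay between -5.43 and -1.66 and between -4.22 and -1.45. Without control replicate 1, 2 or 3 the count was 6, 175 and 22, and without sMaf CKO replicate 1, 2 or 3 it was 3, 11 and 294. The share of rises moved too, from 71.1% to 81.8% under quantile normalization (18 of 22 genes), 56.1% within slide 1 and 48.6% without sMaf CKO replicate 3 (143 rose, 151 fell), and with no filter on dim probes 1 gene passed.

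**Figure D2:**
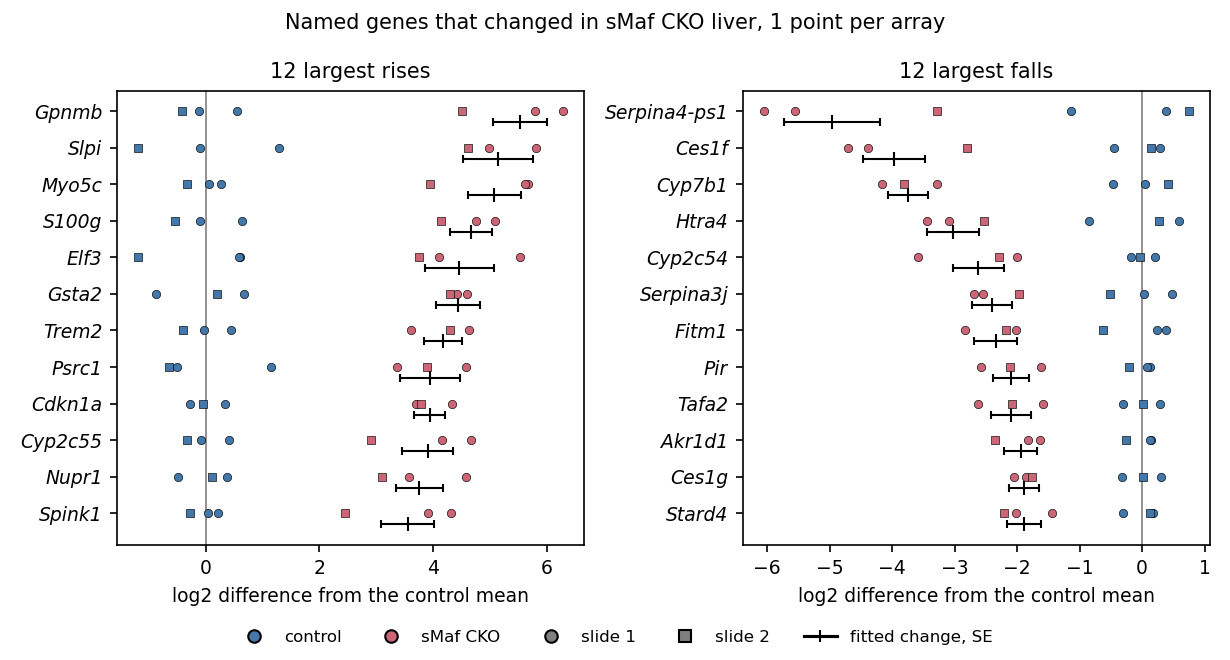
Named genes with the 12 largest fitted rises (left) and 12 largest fitted falls (right) among genes that changed, as the log2 difference of each array from the control mean of that gene (x axis), with colour giving the genotype, shape the slide, and the black mark the fitted change with its SE. The 3 sMaf CKO arrays lie apart from the 3 control arrays for each gene, and the fitted changes of Gpnmb and Myo5c, dim in controls, are not bounds.

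Before the data were examined, 45 lists of genes were fixed for pathways of the liver, factors linked to small Maf proteins and cell types, and 44 had enough tested members. With an inter-gene correlation preset to 0.01, camera called 24 lists, 12 higher and 12 lower in sMaf CKO liver. With a correlation estimated for each list, 0 lists passed (6 at an unadjusted p under 0.05), so the value with an estimated correlation stands beside each call. That setting differs in more than the correlation. For markers of monocyte-derived macrophages the estimate was -0.00111, below the preset value, yet the unadjusted camera p rose from 0.000323 to 0.0205. A call lost under it therefore does not by itself show correlation among members. The rotation test fry, which asks whether members move one way on balance, called 3 lists. Other divisions of the 6 arrays into groups of 3, each mixing the genotypes, gave from 0 to 28 lists with the preset correlation. The list scores of the genotypes did not overlap for 23 of the 44 lists (52.3%, against 10% by chance), 19 of the 24 called lists among them. The called lists with overlapping scores were fatty acid and triglyceride synthesis, cell cycle, interferon response, oxidative phosphorylation and hepatocyte markers. With slide as a block, 23 lists were called. The lipid droplet list was the single one of the 24 to lose its call. Members named below that passed only when adjusted over their list alone, and that are not among its best-ranked members, were chosen after their values were seen.

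Among the CNC and Bach partners of small Maf proteins together with Keap1, 0 of 6 tested genes changed over all genes tested (3 at an unadjusted p under 0.05), and 3 passed when adjusted over the list alone. These were Nfe2l2, which encodes NRF2 (0.68, SE 0.20, adjusted p = 0.167 over all genes), Bach1, a haem-regulated repressor (-1.16, SE 0.33, adjusted p = 0.160), and Keap1, the repressor of NRF2 (-0.79, SE 0.24, adjusted p = 0.182). Nfe2l1, which encodes NRF1, differed by -0.10 (adjusted p = 0.877, with the opposite sign under quantile normalization and spike-in scaling), Nfe2l3 by -0.21 (adjusted p = 0.806, positive under spike-in scaling; -0.51 within slide 1 and 0.37 within slide 2) and Nfe2 by -0.51 (adjusted p = 0.679; -1.13 within slide 1 and 0.72 within slide 2). The list as a whole did not pass (median -0.36, -0.60 within slide 1 and 0.15 within slide 2, -0.10 without sMaf CKO replicate 1, camera adjusted p = 0.406).

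NRF2-linked antioxidant and detoxication genes were lower as a group, with members on both sides. Of 28 tested members, 20 had negative and 8 positive fold changes, with a median of -0.47 (-0.59 within slide 1, -0.19 within slide 2; camera adjusted p = 0.0126). The call was lost with an estimated correlation (adjusted p = 0.555 with an estimated correlation), under quantile normalization (median -0.27, adjusted p = 0.101) and without control replicate 1 (median -0.32, adjusted p = 0.119). The mean over the list was -0.22. List scores were 0.22, -0.11 and -0.11 on control arrays 1, 2 and 3, and -0.32, -0.15 and -0.18 on sMaf CKO arrays 1, 2 and 3. Apart from control array 1 and sMaf CKO array 1, the scores lay close together. Over all genes 1 member rose and 1 fell, and when adjusted over the list alone 4 rose and 8 fell. Hmox1, the inducible haem oxygenase, rose 8.74-fold (log2 fold change 3.13, SE 0.38, adjusted p = 0.0344), whereas Ces1g, a carboxylesterase, fell 3.70-fold (adjusted p = 0.0361). Among members that passed over the list alone were Nqo1, a quinone reductase (-1.66, adjusted p = 0.12 over all genes), Gclc, the catalytic subunit of glutathione synthesis (-1.03, adjusted p = 0.124), the transporter Abcc3 (-1.64, adjusted p = 0.0533) and, in the other direction, the aldo-keto reductase Akr1b7 (2.75, adjusted p = 0.0523). On the same arrays hepatocyte markers had a median of -0.42 (-0.07 within slide 2) and likewise lost their call under quantile normalization. No test compared the NRF2-linked list with them. Of 7 enzymes that produce NADPH, 0 changed over all genes (2 at an unadjusted p under 0.05) and 2 fell when adjusted over the list alone. Those were Me1 (-2.43, SE 0.42, adjusted p = 0.0567) and Idh1 (-1.22, SE 0.24, adjusted p = 0.0750), which both passed with slide as a block (adjusted p = 0.0470 and 0.0402). Their list did not pass (median -0.40, -0.55 within slide 1 and -0.06 within slide 2, camera adjusted p = 0.0701). It passed under 6 other settings, normexp among them, while the median shrank to -0.23 without control replicate 1 (adjusted p = 0.415) or sMaf CKO replicate 1 (adjusted p = 0.132) and to -0.11 under quantile normalization (adjusted p = 0.382).

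Glutathione S-transferases moved apart. Gsta2 rose 21.7-fold (log2 fold change 4.44, SE 0.39, adjusted p = 0.0117) and Gsta1 7.63-fold (2.93, SE 0.26, adjusted p = 0.0117), 2 paralogs whose signals may not be separable here. They were the 2 members of 20 that changed over all genes. Adjusted over the list alone, Gstm2 rose with them (1.29), and Gstm4 (-1.33), Gsta3 (-1.01) and Mgst1 (-0.998) fell. The median of the 20 genes was -0.44 (-0.53 within slide 1, -0.20 within slide 2) but their mean 0.09, and the list did not pass in the direction camera gave, which was down (adjusted p = 0.580). Metallothionein and metal transport genes did not pass either, with 0 of 5 members past limma's test and 0 at an unadjusted p under 0.05 (median -0.15, -0.10 within slide 1 and -0.27 within slide 2, camera adjusted p = 0.780). The median was positive under quantile normalization and spike-in scaling. Slc30a1 (-0.20, adjusted p = 0.735) and Slc39a14 (-0.15, adjusted p = 0.753) each had a second probe of the opposite sign.

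Proteasome subunit genes, which are linked to NRF1, were slightly lower as a group. Of 34 tested subunits, 33 had a negative fold change, with a median of -0.49 (-0.56 within slide 1, -0.35 within slide 2; camera adjusted p = 1.90e-07). No single subunit passed limma's test, either over all genes or adjusted over the list alone (0 of 34, with 13 at an unadjusted p under 0.05). The best-ranked were Psmd1 (-0.80, SE 0.21, adjusted p = 0.151) and Psmd7 (-0.74, SE 0.21, adjusted p = 0.159). The call was lost with an estimated correlation (adjusted p = 0.379 with an estimated correlation) and with fry (adjusted p = 0.0581), and the median was -0.23 under quantile normalization, where the list still passed (adjusted p = 0.000486). Markers of hepatocytes had a median of -0.42 over all arrays and -0.08 under quantile normalization, where they lost their call. Within slide 2, 1 array against 1, their median was -0.07, with list scores of 0.06 in control and -0.15 in sMaf CKO liver. No test compared the 2 lists.

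Genes of cholesterol synthesis and uptake had the lowest median among the 44 lists tested. All 21 tested members were lower in sMaf CKO liver, with a median log2 fold change of -1.20 (camera adjusted p = 2.54e-08, adjusted p = 0.465 with an estimated correlation). The median was -1.47 within slide 1 and -0.46 within slide 2, and -0.78 without sMaf CKO replicate 1. Over all genes 0 passed limma's test (14 at an unadjusted p under 0.05), and 9 fell when adjusted over the list alone. Cyp51, a sterol demethylase, differed by -1.59 (SE 0.38, adjusted p = 0.116) and Insig1, a sterol sensor of the endoplasmic reticulum, by -1.32 (SE 0.37, adjusted p = 0.157). Genes of fatty acid and triglyceride synthesis were also lower as a group, with 18 of 20 members negative and a median of -0.60 (-0.78 within slide 1, -0.31 within slide 2; camera adjusted p = 0.000219, adjusted p = 0.465 with an estimated correlation). The list scores of the genotypes overlapped, with -0.14 on sMaf CKO array 2 and -0.20 on control array 3. The lowest score was -1.13 on sMaf CKO array 1. No member passed limma's test over all genes or over the list alone (8 at an unadjusted p under 0.05). The best-ranked were the desaturase Fads1 (-0.84, SE 0.25, adjusted p = 0.177) and the elongase Elovl5 (-1.06, SE 0.34, adjusted p = 0.194). Markers of hepatocytes had a median of -0.42 on the same arrays (-0.59 within slide 1, -0.07 within slide 2).

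Lipid droplet and lipoprotein genes were higher as a group, by a call that did not hold with slide as a block. Of 19 members, 1 rose over all genes and 5 when adjusted over the list alone. Cidea, a protein that enlarges lipid droplets, rose 5.91-fold (log2 fold change 2.56, SE 0.30, adjusted p = 0.0290), and the others were Cidec (2.61), G0s2 (1.46), Cd36 (1.40) and Vldlr (1.04). The median was 0.32 (0.29 within slide 1, 0.17 within slide 2; camera adjusted p = 0.0433, 0.0651 with slide as a block, adjusted p = 0.307 with an estimated correlation). The call was also lost without control replicate 2 (median 0.09, adjusted p = 0.0848) and without sMaf CKO replicate 3 (median 0.16, adjusted p = 0.139). It was lost as well with normexp (adjusted p = 0.0572), array weights (adjusted p = 0.0840) and fry (adjusted p = 0.0530), and within slide 1 (adjusted p = 0.0737). Genes of fatty acid oxidation and targets linked to PPARalpha did not move as a group (25 tested, median -0.25 but mean 0.06, -0.31 within slide 1 and 0.02 within slide 2, camera adjusted p = 0.409). The median was positive under quantile normalization and spike-in scaling. Fgf21, a hepatokine of fasting and stress, rose 10.69-fold (log2 fold change 3.42, SE 0.43, adjusted p = 0.0367). Adjusted over the list alone Pdk4 rose too (3.79), and Ppargc1b (-1.24) and Ppara (-1.03) were among the members that fell.

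Bile acid synthesis and transport genes were lower as a group. Of 17 members, Cyp7b1 fell over all genes, and adjusted over the list alone 8 fell and 1, the exporter subunit gene Slc51b (1.65), rose. Members that passed over the list alone included Slc10a1, the uptake transporter NTCP (-1.79), the sterol transporter gene Abcg8 (-1.91) and Cyp8b1 (-1.71). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -0.43 (adjusted p = 0.538). The median was -0.73 (-0.75 within slide 1, -0.56 within slide 2; camera adjusted p = 3.01e-05, adjusted p = 0.364 with an estimated correlation). Xenobiotic cytochrome P450 genes were also lower, with 23 of 27 members negative and a median of -0.61 (-0.79 within slide 1, -0.45 within slide 2; camera adjusted p = 3.01e-05, adjusted p = 0.465 with an estimated correlation). The median was -0.25 under quantile normalization. Cyp2c55 rose 14.9-fold (log2 fold change 3.90, SE 0.45, adjusted p = 0.0269) and Cyp2c54 fell 6.15-fold (-2.62, SE 0.41, adjusted p = 0.0486), and adjusted over the list alone 1 rose and 8 fell. Paralogs in this family can share signal. Both lists hold genes expressed mainly in hepatocytes, whose markers had a median of -0.42 on the same arrays. Within slide 2, 1 array against 1, those markers had a median of -0.07, with list scores of 0.06 in control and -0.15 in sMaf CKO liver. Under quantile normalization they lost their call while both lists kept theirs. No test compared them with these lists.

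Urea cycle and amino acid catabolism genes were lower throughout. All 20 tested members had negative values, with a median of -0.80 (-0.99 within slide 1, -0.62 within slide 2; camera adjusted p = 1.90e-07, adjusted p = 0.465 with an estimated correlation). The median was -0.47 without sMaf CKO replicate 1 and -0.43 under quantile normalization. These too are hepatocyte genes, with Hpd in both lists, and all 9 hepatocyte markers were lower on the same arrays. Their median was -0.42, and -0.07 within slide 2, where the list scores were 0.06 in control and -0.15 in sMaf CKO liver. Tdo2, which starts tryptophan breakdown, fell 3.64-fold (log2 fold change -1.86, SE 0.25, adjusted p = 0.0382). Adjusted over the list alone 4 fell, Tdo2, Arg1 (-1.30), Oat (-1.73) and Gls2 (-1.22). Methionine, choline and one-carbon genes did not pass as a group (21 tested, median -0.38, -0.54 within slide 1 and -0.24 within slide 2, camera adjusted p = 0.0525). The list passed under 8 other settings, normexp among them, but had a median of -0.25 without sMaf CKO replicate 1 (adjusted p = 0.186) and -0.24 under quantile normalization (adjusted p = 0.222). Chka, choline kinase, rose 4.80-fold (log2 fold change 2.26, SE 0.36, adjusted p = 0.0493). Members that fell when adjusted over the list alone were Ahcy (-1.68), Mat1a (-1.16) and Aldh1l1 (-1.24). Of 13 genes of glucose metabolism 0 passed over all genes (5 at an unadjusted p under 0.05), and 2 rose over the list alone, Igfbp1 (2.34, SE 0.50, adjusted p = 0.0912) and the hexokinase Hk2 (1.19, SE 0.24, adjusted p = 0.0832, 0.0482 with slide as a block). Their list had a median of -0.41 (-0.43 within slide 1, -0.05 within slide 2) and did not pass (camera adjusted p = 0.720).

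Genes linked to p53 rose as a group, with the lowest camera p among the 44 lists tested. Of 14 members, 13 were higher, 3 rose over all genes and 11 when adjusted over the list alone. Cdkn1a rose 15.3-fold (log2 fold change 3.94, SE 0.27, adjusted p = 0.00857), Phlda3, an inhibitor of AKT signalling, 7.09-fold (2.83, SE 0.27, adjusted p = 0.0134) and Ccng1, cyclin G1, 2.56-fold (1.35, SE 0.21, adjusted p = 0.0493). The median was 1.06 (1.08 within slide 1, 1.26 within slide 2; camera adjusted p = 7.08e-11, fry adjusted p = 0.0254), but adjusted p = 0.307 with an estimated correlation. Genes of the integrated stress response were higher too, with a median of 0.84 over 18 members (1.09 within slide 1, 0.73 within slide 2; camera adjusted p = 9.87e-07, adjusted p = 0.307 with an estimated correlation). Nupr1 rose 13.5-fold (log2 fold change 3.75, SE 0.41, adjusted p = 0.0218) and the stress-induced factor Atf3 10.9-fold (3.45, SE 0.49, adjusted p = 0.0402), while Atf4 itself differed by 0.01 (adjusted p = 0.988). Adjusted over the list alone 8 rose, Ddit3 among them (2.07), and 1 fell, Chac1 (-1.30), a glutathione-degrading enzyme.

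Cell cycle genes were higher as a group, 21 of 23 members, with a median of 1.17 (0.77 within slide 1, 1.92 within slide 2; camera adjusted p = 9.56e-07, adjusted p = 0.465 with an estimated correlation). The median was 0.66 without control replicate 3, and the list scores of the genotypes overlapped. The overlap came from control array 2, with a score of 1.03 against -0.28 and -0.75 on the other controls, and the same array stood apart in erythroid markers (1.38 against -0.93 and -0.45). Over all genes 0 passed limma's test (10 at an unadjusted p under 0.05), and 2 mitotic genes rose over the list alone, Aurka (2.29, SE 0.54, adjusted p = 0.114) and Cdc20 (2.29, SE 0.56, adjusted p = 0.123). Immediate early genes were higher too, with a median of 0.85 over 16 members (1.01 within slide 1, 0.50 within slide 2; camera adjusted p = 0.000218, adjusted p = 0.307 with an estimated correlation), and Atf3, Egr2 (3.30) and Jun (1.98) rose over the list alone. Neither the unfolded protein response nor heat shock proteins moved as a group. For the first, 0 of 16 members passed (2 at an unadjusted p under 0.05; median -0.16, -0.19 within slide 1 and -0.01 within slide 2, camera adjusted p = 0.333), with Herpud1 at -0.77 (adjusted p = 0.229) and Edem1 at -0.70 (adjusted p = 0.234). For the second, 0 of 12 passed, also at an unadjusted p under 0.05 (median -0.06 but mean 0.06, 0.07 within slide 1 and -0.08 within slide 2, camera adjusted p = 0.812), with Hspb1 at 0.75 (adjusted p = 0.407) and Hsp90aa1 at 0.74 (adjusted p = 0.413). Both medians turned positive under quantile normalization and spike-in scaling.

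Macrophage genes were higher in sMaf CKO liver. Of 8 markers of monocyte-derived macrophages, Trem2 and Gpnmb rose over all genes and over the list alone, and the other 6 did not pass. The list median was 0.92 (0.87 within slide 1, 0.81 within slide 2; camera adjusted p = 0.000835, fry adjusted p = 0.0254, but adjusted p = 0.307 with an estimated correlation). It was 0.58, with an adjusted p of 0.188, over probes well above background on all 6 arrays, a filter that removes both members that passed, Gpnmb and Trem2. All 12 markers of Kupffer cells and macrophages had positive values (median 0.77, 0.62 within slide 1 and 1.0 within slide 2; camera adjusted p = 1.40e-05, adjusted p = 0.465 with an estimated correlation), and the median was 0.50 without control replicate 3. Over all genes 0 passed (6 at an unadjusted p under 0.05) and over the list alone 3 rose, the scavenger receptor Marco (3.73, SE 0.77, adjusted p = 0.0859, 0.0107 with slide as a block), Ms4a7 (1.51, SE 0.42, adjusted p = 0.157) and Cd5l (0.88). The joint list of acute phase and inflammation genes did not move as a group (20 tested, median -0.12 but mean 0.19 and up by camera, adjusted p = 0.965; -0.16 within slide 1, 0.02 within slide 2). At an unadjusted limma p under 0.05, 3 members were higher, Ccl2, Lcn2 and Hpx (0.70). The 4 lower ones were the acute phase genes Orm2 (-1.17), Orm1 (-1.15), Fga (-0.72) and Crp (-0.61), so the list does not speak for inflammation genes alone. The median of the list was positive under quantile normalization and spike-in scaling. Adjusted over the list alone 2 members rose, the chemokine Ccl2 (2.90, SE 0.49, adjusted p = 0.0533, 0.0234 with slide as a block) and the lipocalin Lcn2 (2.38, SE 0.46, adjusted p = 0.0746). Interferon response genes were slightly higher (19 tested, median 0.29, 0.29 within slide 1 and 0.24 within slide 2; camera adjusted p = 0.0112, adjusted p = 0.465 with an estimated correlation). That call was lost without control replicate 2 (adjusted p = 0.0822), control replicate 3 (median 0.10, adjusted p = 0.0733) or sMaf CKO replicate 1 (adjusted p = 0.0538). None of its members passed over all genes or the list alone (4 at an unadjusted p under 0.05), with Oasl1 at 0.92 (adjusted p = 0.126) and Cxcl10 at 1.59 (adjusted p = 0.154).

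Markers of stellate cells and genes of the extracellular matrix were higher as well. All 12 stellate markers had positive values (median 0.51, 0.59 within slide 1 and 0.75 within slide 2; camera adjusted p = 2.73e-05, fry adjusted p = 0.0254, but adjusted p = 0.307 with an estimated correlation). Over all genes 0 passed (5 at an unadjusted p under 0.05) and over the list alone 5 rose, Pdgfra (1.39, SE 0.28, adjusted p = 0.0854), Lum (1.26, SE 0.27, adjusted p = 0.0937), Hgf (1.07), Reln (0.84) and Lrat (0.79). Of 19 matrix and fibrosis genes, Mmp13, a collagenase measured on 2 of 3 control arrays, rose 7.03-fold (log2 fold change 2.81, SE 0.40, adjusted p = 0.0402), or 5.50-fold with the dim array raised likewise, and Mmp2 (1.38) and Mmp12 passed with it over the list alone. Mmp12 was not well above background on any control array and rose at least 6.37-fold. Their median was 0.53 (0.48 within slide 1, 0.51 within slide 2; camera adjusted p = 0.000100, adjusted p = 0.339 with an estimated correlation), and the collagen gene Col1a1 differed by 0.86 (adjusted p = 0.224). Cholangiocyte and ductular markers were higher (13 tested, median 0.63, 0.62 within slide 1 and 0.64 within slide 2; camera adjusted p = 0.00174, adjusted p = 0.465 with an estimated correlation). Their median was 0.38 without sMaf CKO replicate 1, 0.41 without control replicate 2 and 0.39 after normexp background correction. Over all genes 0 passed (5 at an unadjusted p under 0.05), and Krt8 (1.07, SE 0.26, adjusted p = 0.124), Krt18 (0.995, SE 0.25, adjusted p = 0.127), 2 keratins that hepatocytes also express, and Cldn7 (1.48) rose over the list alone. Fetal liver and tumour-associated genes were higher (9 tested, median 0.94, 1.21 within slide 1 and 1.23 within slide 2; camera adjusted p = 4.80e-05, adjusted p = 0.307 with an estimated correlation). Spink1 rose 11.7-fold (adjusted p = 0.0382), and over the list alone Tff3 (3.57), Ly6d (3.09), Afp (2.65) and Gpc3 (0.94) passed too.

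Markers of hepatocytes were lower as a group, all 9 of them (median -0.42, -0.59 within slide 1 and -0.07 within slide 2; camera adjusted p = 0.00371, adjusted p = 0.555 with an estimated correlation). Within slide 2 the list scores were 0.06 on the control and -0.15 on the sMaf CKO array, a wider gap than the median there. The call was lost under quantile normalization (median -0.08, adjusted p = 0.176), and the median was -0.22 without sMaf CKO replicate 1 and -0.64 without sMaf CKO replicate 3. Over all genes 0 passed (2 at an unadjusted p under 0.05), and over the list alone Serpina1c fell (-1.31, SE 0.28, adjusted p = 0.0940). The other cell types gave no call. Endothelial markers had a median of -0.14 over 12 members (-0.16 within slide 1 and 0.16 within slide 2, positive under quantile normalization and spike-in scaling, camera adjusted p = 0.730), with Kdr at -0.56 (adjusted p = 0.380) and Stab2 at -0.46 (adjusted p = 0.424). Neutrophil markers had a median of 0.09 over 9 members (0.34 within slide 1, 0.05 within slide 2, camera adjusted p = 0.484), with Retnlg at 0.90 (adjusted p = 0.192) and S100a9 at 0.49 (adjusted p = 0.436). T and NK cell markers had a median of 0.42 over 12 members (0.52 within slide 1, 0.24 within slide 2, camera adjusted p = 0.580), with Ncr1 at -0.55 (adjusted p = 0.224) and Cd8a at 1.30 (adjusted p = 0.464). B and plasma cell markers had a median of 0.13 over 7 members (0.09 within slide 1, 0.17 within slide 2, camera adjusted p = 0.720), with Jchain at 0.37 (adjusted p = 0.747) and Mzb1 at -0.26 (adjusted p = 0.709). Erythroid markers had a median of 0.17 over 8 members (0.24 within slide 1, 0.55 within slide 2, camera adjusted p = 0.722), with Alas2 at 0.77 (adjusted p = 0.417) and the erythroid factor Klf1 at -1.56 (adjusted p = 0.144, past the threshold over the list alone). Markers of pancreatic acinar tissue had a median of -0.20 over 7 members (-0.40 within slide 1, 0.13 within slide 2, positive under spike-in scaling, camera adjusted p = 0.623), with Amy2a5 at -0.62 (adjusted p = 0.217) and Cela3b at 0.65 (adjusted p = 0.370). In these 6 lists 0 members passed limma's test over all genes, and 0, 1, 1, 0, 1 and 1 members respectively had an unadjusted p under 0.05. Of adipose markers 2 were tested, too few for the list test, Car3 (-1.35, limma adjusted p = 0.0705) and Fabp4 (0.45, adjusted p = 0.350). In control liver Car3 (log2 level 7.54) was about as bright as the hepatocyte marker Hpd (7.12) and far brighter than Fabp4 (2.93). Its fall is therefore not read as a change in adipose tissue.

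**Figure D3:**
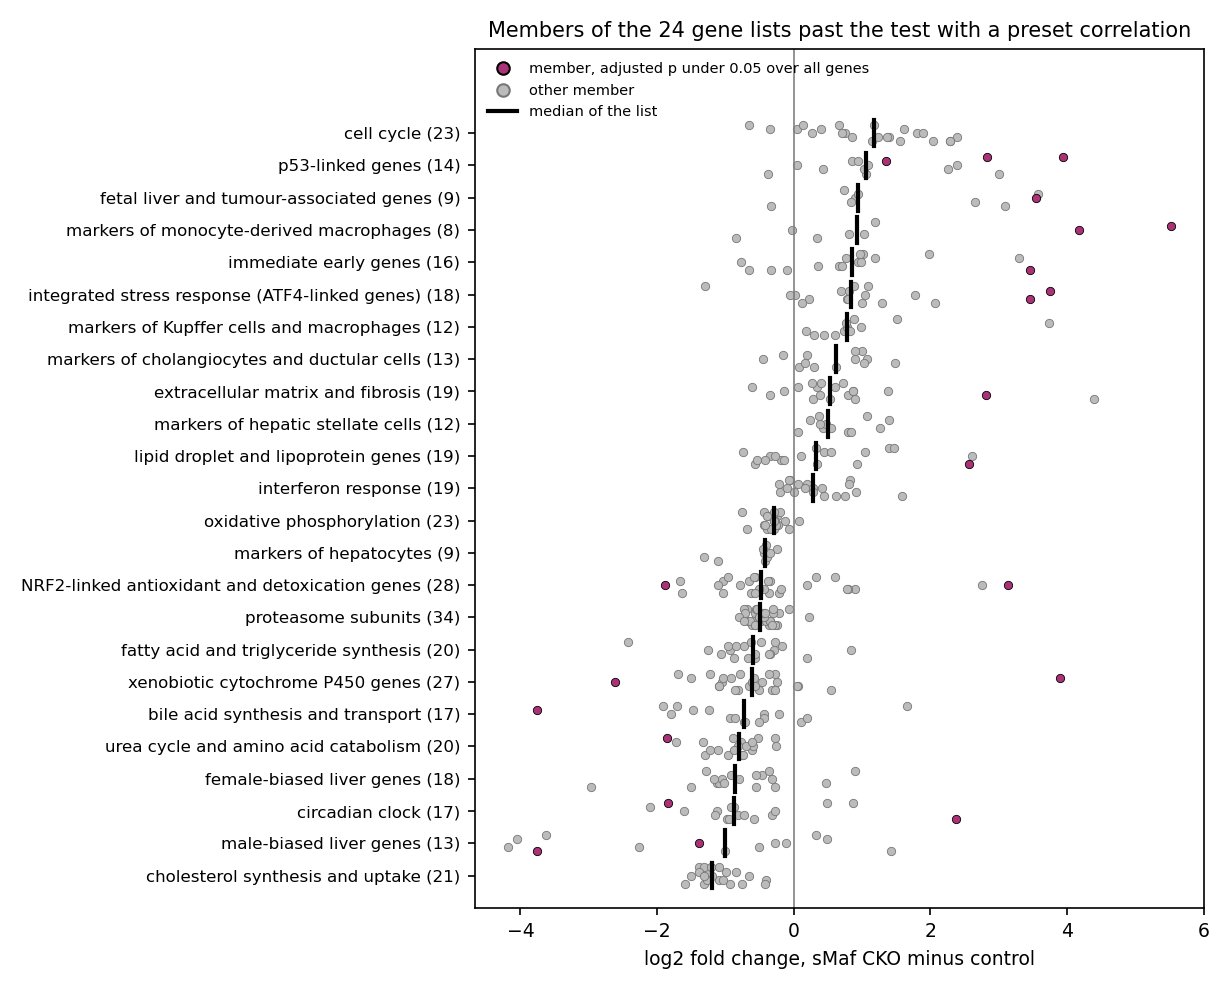
Log2 fold change (sMaf CKO minus control, x axis) of each tested member of the 24 lists that camera called with a preset correlation, with the number of members in parentheses, members with an adjusted p under 0.05 over all genes in purple and the list median as a black line. The points of Gpnmb and Mmp12, dim in controls, are fitted changes and not bounds. Medians run from -1.20 for cholesterol synthesis and uptake to 1.17 for the cell cycle, and 0 of the 24 lists passed with an estimated correlation.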

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

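Scaling on spike-ins and the fits within each slide were chosen after seeing the data, and the other alternatives before. The direction of all 37 named genes that changed was the same under every other scaling, filter and model that measured them, and among subsets of the arrays it is fixed by groups that do not overlap. The number called moved widely. Against 114 genes (81 rose, 33 fell), 74 changed with normexp (53 and 21), 22 with quantile normalization (18 and 4), 252 with median scaling (171 and 81), 267 over probes well above background on all 6 arrays (168 and 99), 1 with no filter on dim probes (0 and 1), 340 with slide as a block (209 and 131), 472 with array weights (271 and 201), 308 with trend and robust settings (204 and 104), 12 with spike-in scaling (9 and 3), 196 within slide 1 (86 fell) and 3 at an adjusted p under 0.01 (2 and 1). The array weights depend on the order of the genes, since limma updates them gene by gene when values are missing, and with the order reversed 377 genes changed (224 and 153). The authors' value table gave 112 and the mean of a gene's probes 104, and a minimum log2 fold change of 1 removed no gene. Of the 114, 61 passed with normexp, 22 with quantile normalization, 114 with median scaling, slide as a block or array weights, and 71 within slide 1. Leaving out 1 array gave 3 to 294 genes (2 to 147 rose, 1 to 151 fell). The stricter filter tested 17237 genes and the run without a filter 32301, and the cause of the shifts was not tested. Scan date was not run as a block, since all arrays share 1 date.

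Whether the replicate numbers of the labels pair the samples cannot be told from so few arrays. Same-numbered arrays deviated from their group means together at r = 0.0634, 0.166 and 0.424, and differently numbered arrays at r = -0.372 to 0.292. The highest of the latter was between sMaf CKO array 1 and control array 2, above the value of array 1 with its own number. With the replicate block, 291 genes changed (193 rose, 98 fell), 108 of the 114 among them, and Mafg passed (-4.69, adjusted p = 0.0256). It changed the number of lists called by 0 (24).

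Mafg lay between -5.66 and -3.86 when 1 array was left out. It passed the threshold with normexp (-3.78), median scaling (-4.72), the stricter filter (-4.69), slide as a block (-4.69), array weights (-5.58) and within slide 1 (-5.55), and was -2.99 within slide 2. Maff lay between -0.37 and 0.52 without 1 array and at -0.25 with array weights. Mafk lay between -0.0701 and 0.44 without 1 array and at -0.29 within slide 2. None of the Maff and Mafk values passed.

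The 24 list calls numbered 22 to 27 under the other scalings, filters, models and subsets of arrays, but 0 with an estimated correlation and 3 with fry. NRF2-linked genes lost their call with quantile normalization (-0.27), with an estimated correlation and with fry (median -0.47 in both), and without control replicate 1, with -0.60 to -0.32 over arrays left out, and their median was -0.19 within slide 2. Proteasome subunits lost theirs with an estimated correlation and with fry (median -0.49 in both), and their median was -0.35 within slide 2. The cause of these changes was not tested.

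For the following lists the direction of camera's test against other genes turned under an alternative, at times without a change in the sign of the median. Ribosomal proteins alone passed in the new direction. With quantile normalization the medians were 0.03 for metal genes, 0.10 for fatty acid oxidation, -0.0385 for glucose metabolism, 0.0547 for the unfolded protein response, 0.28 for ribosomal proteins (adjusted p = 0.000408) and 0.0234 for oxidative phosphorylation, which lost its call. Acute phase and inflammation genes turned with normexp (-0.11), the stricter filter (-0.12) and array weights (-0.31). Array weights also turned B cell markers (-0.19). The rotation test fry asks another question, whether members moved on balance from no change, and its sign differed from camera's for inflammation genes (median -0.12), glutathione S-transferases (-0.44) and heat shock proteins (-0.0592), none of which passed. The mean of a gene's probes turned metal genes (0.0363) and heat shock proteins (-0.16), within slide 1 metal genes turned (-0.10), and spike-in scaling turned ribosomal proteins (0.25) and erythroid markers (0.50). Without 1 array, whether or not the test turned, the medians ran from -0.63 to -0.21 for glutathione S-transferases, -0.22 to -0.00549 for metal genes, -0.31 to -0.0758 for fatty acid oxidation, -0.57 to -0.00308 for glucose metabolism, -0.21 to 0.11 for heat shock proteins, -0.35 to 0.10 for inflammation, -0.17 to 0.0523 for ribosomal proteins, -0.25 to 0.54 for neutrophil markers, -0.17 to 0.77 for T and NK cell markers, -0.0826 to 0.36 for B cell markers, -0.21 to 0.0269 for endothelial markers and -0.17 to 0.82 for erythroid markers, which passed without control replicate 2 (adjusted p = 0.00652).

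Single genes that turned were all short of the threshold. With quantile normalization Nfe2l1 was 0.10, Rpl11 0.11 and Rps2 0.0784, and with normexp Ncr1 was 0.0257. With spike-in scaling Nfe2l1 was 0.22, Nfe2l3 0.11, Mzb1 0.0612, Rpl11 0.0301, Slc30a1 0.13 and Slc39a14 0.17. With array weights Jchain was -0.0196, and with the mean of probes Slc30a1 was 0.0363 and Slc39a14 0.0772. Without 1 array Jchain lay between -0.0759 and 0.86, Mzb1 between -0.44 and 0.0753, Nfe2 between -1.10 and 0.0583, Nfe2l1 between -0.23 and 0.10 and Nfe2l3 between -0.61 and 0.0632. The values within the slides had opposite signs for Nfe2 (-1.13 and 0.72), Nfe2l3 (-0.51 and 0.37), Mzb1 (-0.48 and 0.17) and Slc30a1 (-0.32 and 0.05). Between 58.0% and 73.6% of probes were well above background on an array.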

Other observations

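The tests on cell type scores and on the clock were chosen after the values were seen. Genes of the circadian clock shifted in opposite directions in sMaf CKO liver. Arntl, the activator BMAL1, rose 5.19-fold (log2 fold change 2.37, SE 0.32, adjusted p = 0.0382 with limma) and Per3, a repressor of the feedback loop, fell 3.59-fold (-1.84, SE 0.27, adjusted p = 0.0459). Over 17 clock genes the median was -0.87 (-0.81 within slide 1, -0.72 within slide 2; camera adjusted p = 0.00265, adjusted p = 0.307 with an estimated correlation), and adjusted over the list alone 2 rose and 8 fell, Clock (0.87) being the second that rose. Male-biased liver genes were lower, with a median of -1.001 over 13 members (-1.18 within slide 1, -0.65 within slide 2, -0.66 without sMaf CKO replicate 1; camera adjusted p = 0.000644, adjusted p = 0.307 with an estimated correlation). Of these Cyp7b1 and Ugt2b38 (-1.39, SE 0.21, adjusted p = 0.0483) fell over all genes, and 7 fell and 1, C6 (1.43), rose over the list alone. Female-biased liver genes were lower as well, with a median of -0.86 over 18 members (-0.81 within slide 1, -0.57 within slide 2; camera adjusted p = 0.000218, adjusted p = 0.307 with an estimated correlation). None of them passed over all genes or the list alone (8 at an unadjusted p under 0.05), with A1bg at -2.96 (SE 0.83, adjusted p = 0.157) and Abcd2 at -1.12 (SE 0.30, adjusted p = 0.152). Hepatocyte markers had a median of -0.42 on the same arrays (-0.07 within slide 2), and no test compared these lists with them. Xist was well above background on all 6 arrays, and of the Y-linked genes Uty, Kdm5d, Ddx3y and Eif2s3y only Eif2s3y was, on control array 3 (log2 level -2.32). This is the pattern of female liver, though the labels give no sex and the signal of Eif2s3y on that array is unexplained.

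Genes of oxidative phosphorylation were slightly lower, 22 of 23 members, with a median of -0.29 (-0.42 within slide 1, -0.04 within slide 2; camera adjusted p = 0.00518, adjusted p = 0.724 with an estimated correlation). The call was lost with quantile normalization (median 0.02), with spike-in scaling (median 0.04) and without sMaf CKO replicate 1 (median -0.08, adjusted p = 0.468), and 0 members passed (2 at an unadjusted p under 0.05), with Sdha at -0.76 (adjusted p = 0.151) and Sdhb at -0.68 (adjusted p = 0.266). On the same arrays hepatocyte markers had a median of -0.42 (-0.07 within slide 2), and no test compared the 2 lists. Ribosomal protein genes did not move as a group (24 tested, median -0.07, -0.15 within slide 1 and 0.13 within slide 2, camera adjusted p = 0.580, higher under quantile normalization), and 0 members had an unadjusted p under 0.05, with Rps2 at -0.33 and Rpl11 at -0.29. Neither zone of the lobule gave a call in the main test, while both lists passed after normexp and neither did under quantile normalization (adjusted p = 0.465 and 0.545) or with slide as a block (adjusted p = 0.156 and 0.271, the periportal value first in each pair). Periportal genes had a median of -0.60 over 12 members (-0.66 within slide 1, -0.17 within slide 2, camera adjusted p = 0.133), and pericentral genes of -0.30 over 13 members (-0.46 within slide 1, -0.07 within slide 2, positive under spike-in scaling, camera adjusted p = 0.231). Over their lists alone Cdh1 rose (1.09, SE 0.23) and Pigr (-1.25, SE 0.33) and Gls2 (-1.22) fell among periportal genes, and Axin2 rose (1.11, SE 0.26) and Oat fell (-1.73, SE 0.47) among pericentral genes.

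With 3 arrays against 3 there are 10 divisions of the arrays, too few for a share under 0.05. For genes, the real division gave 114 and the highest other gave 1, so 1 of the 10 divisions was as large. For lists called with the preset correlation, the real division gave 24 and the highest other, control replicates 1 and 3 with sMaf CKO replicate 2 against the rest, gave 28, so 2 of the 10 were as large. That division does not follow the slides. The remaining divisions, which also mix the genotypes, gave 19, 15, 15, 13, 9, 7, 6 and 0 lists. Camera with the preset correlation thus often called lists in groups that mix the genotypes, and the count of 24 does not by itself mark the genotype.

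Macrophage and stellate markers were higher and hepatocyte markers lower by calls that were lost with an estimated correlation (adjusted p = 0.307 to 0.555), and the hepatocyte scores of the genotypes overlapped. A lower share of hepatocytes with other cell types unchanged would raise all their markers alike, but the Kupffer score exceeded the endothelial score by 1.075 more in sMaf CKO than in control liver (SE 0.293), with an endothelial difference of -0.10 (SE 0.12), which argues against it as the whole cause. A difference between slides would leave no gap within a slide, and the Kupffer difference was 1.264 within slide 2 and 0.836 within slide 1. Each slide holds the genotypes in equal numbers, so a shift of a whole slide cancels by design. These values largely restate the whole difference and are no separate test. A change in macrophages with the genotype stays open as a hypothesis, untested here, which counts of these cells in liver sections would decide. Not all markers rose, as Ly6c2 of the monocyte-derived list was lower (-0.85, unadjusted p = 0.0463 with limma) and Cx3cr1 differed by -0.03.

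Mafg kept more signal in sMaf CKO replicate 3 (14.8% of the control mean), and the change in 200 genes picked on the other 4 arrays was 0.6473 of its size there for that number-matched pair (SE 0.0344). Genes picked for a large t on some arrays tend to change less on others, so a value under 1 does not by itself show shrinkage. Over probes well above background on all 6 arrays, the SD of the slide 2 control array was 1.005 times the mean of the slide 1 controls. Signals of these bright probes were thus not narrower there, but dimmer probes are not covered. Both slide 2 arrays had fewer probes well above background (58.04% and 58.65%) than the slide 1 arrays (66.13% to 73.57%). Whether changes on slide 2 were compressed beyond the effect of picking is not decided. For the remaining Mafg, replicate 2, with 1.22% left, had a value of 0.507 (SE 0.0387) and replicate 1, with 3.20% left, 1.06 (SE 0.0519). Each value rests on 1 liver per genotype in number-matched arrays that may not be true pairs. The SE is over genes and not livers, so the order written down beforehand decides nothing. An effect of the remaining Mafg and differences between single livers cannot be told apart here.

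The opposite shifts of clock genes could reflect a different time of day at collection. The set taken as the positive arm had 3 tested genes, Arntl (2.37), Clock (0.87) and Nfil3 (0.49), and the set taken as driven by them had 10. Their scores moved apart by 2.361 (SE 0.513), the driven genes differing by -1.12 (SE 0.31), as a shift in phase would give. The score of so small a positive arm rests largely on Arntl. A change of the clock by the genotype would give the same, the labels state no time of collection, and the explanations cannot be told apart here.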
